A study of Homo sapiens and Mus musculus with 49 samples.

How the data were processed

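The series holds 49 libraries from leukaemia cell lines, 25 of ChIP-seq, 18 of RNA-seq and 6 of PRO-seq (precision run-on sequencing, which maps engaged RNA polymerase). Values were analysed for 12 RNA-seq libraries, 6 ChIP-seq peak tables and all 6 PRO-seq libraries. The other 6 RNA-seq libraries (AF9 and AF4 knockdowns and their controls) and 19 ChIP-seq libraries were not analysed here. The submitters' processing notes name BWA, Bowtie, HOMER and the human build hg19, without versions or the step each served, and the RNA quantifier was not given in the sources used here. Groups came from the labels, and knockdowns were made by RNA interference in HEL cells per the labels' protocols.

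The deposited RNA-seq table holds RPKM values (reads scaled to transcript length and library size) for 23600 entries, computed by the authors, with the gene annotation not stated. Its column names put 2 control and 2 knockdown libraries in each of 3 sets (ENL, AFF4, DOT1L). The control columns that name no gene were taken as the controls of the ENL set, which the labels do not state. The table gives 2366 entries under joint names of several genes, whose reads cannot be told apart, among them DOT1L, listed together with MIR6789 and PLEKHJ1. It repeats 234 names on more than 1 entry and holds 22 names that a spreadsheet had turned into dates, which match no listed gene. The labels call the libraries strand-specific, but the counting is not stated to use strand, so entries joined with an antisense gene are uncertain.

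Absolute depth is unknown for RPKM values. From the smallest steps between low values, the relative depth of the libraries was 0.679 to 1 of the deepest, control replicate 1 of the AFF4 set. RPKM summed to 264108 to 307046 per library, 10431 to 10862 entries reached 1 RPKM, and the 10 highest entries held 8.65% to 10.6% of each sum.

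Entries with at least 1 RPKM in at least 2 libraries were kept (11439). They were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, in a joint fit of the 12 libraries with library set as covariate, eBayes with an intensity trend, and Benjamini-Hochberg adjusted p under 0.05. The fit had 6 residual degrees of freedom and 2.72 prior degrees of freedom. Log2 fold changes are on this scale, which understates the change of low genes, and folds given beside RPKM are ratios of mean RPKM. On simulated changes among the 11439 genes, the fit recovered 40.3%, 85.1% and 98.5% of genes changed 1.5-, 2- and 3-fold in the ENL comparison, 52.2%, 80.6% and 98.5% in the AFF4 comparison, and 47.8%, 91.0% and 100% in the DOT1L comparison, with 3.87%, 3.75% and 4.22% false calls. The simulated noise was independent between genes and, for each gene, equal in all 12 libraries. These rates therefore do not cover unequal spread between the arms or noise shared across genes.

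Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 26 lists with at least 5 kept members were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists. They comprised the super elongation complex and P-TEFb, P-TEFb inhibition and pausing factors, the PAF1 complex, the MLL complex, canonical MLL fusion targets, HOX cluster genes, immediate early genes, heat shock response, erythroid, megakaryocyte and platelet, myeloid and monocyte, and T and B lymphoid genes, interferon response, NF-kB and inflammatory genes, S phase genes, G2/M genes, p53 targets, MYC target and nucleolar genes, unfolded protein and integrated stress response, cholesterol synthesis and uptake, glycolysis and hypoxia genes, oxidative phosphorylation genes, ribosomal protein genes, replication-dependent histone genes, RNA polymerase II subunits and JAK-STAT5 response genes. The targeted genes and relatives (4 kept), the DOT1L complex (4 kept) and epithelial and fibroblast genes (3 kept) were too short to test.

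Named genes were, for each knockdown, the targeted gene and its relatives, the 6 passing genes with the largest rise and the 6 with the largest fall among those with at least 5 RPKM in the higher arm and both knockdown libraries on the same side of both controls, and the 3 members with the smallest p in the direction of each passing list. Genes outside the rule are marked as chosen after their values were seen, and some genes the rule takes are not reported here.

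The PRO-seq files give coverage and tag signal on each strand around start sites, averaged by HOMER in 10-bp bins over a 4000-bp window of hg19 per the file headers. Normalization between libraries is not stated. The sense maximum, the mean from 0 to +250 bp (proximal), the mean from +1000 bp (downstream) and their ratio were computed in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Figures used matplotlib 3.10.9.

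The deposited peak tables give each peak's position, the authors' score and a peak height (signal), 1 library per table. Peak caller, control library and threshold were not given in the sources used here, and scores were used only to rank peaks within a table. Peaks sharing at least 1 bp were counted as overlapping, with 95% Wilson intervals that cover counting error only, and the overlap code was checked against a brute-force count on simulated intervals. The build of the mouse table was not stated, so no mouse coordinates are given. With no hg19 annotation, peaks were not assigned to genes, and the planned tests of genes with an MLL-N peak, target-gene overlaps and genes shared between mouse and human were not run.

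Alternatives covered the pseudocount, the filter, quantile and median scaling, all controls pooled without library set, fits of each set alone, eBayes without trend, a replicate block, each library left out in turn, a 1.5-fold minimum, other set tests (camera with an estimated correlation, and fry), other PRO-seq windows and scaling, and other peak thresholds and overlap rules.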

Results

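RNA-seq, PRO-seq and ChIP-seq were collected to ask how partners of MLL1 fusion proteins act on RNA polymerase II. The partners are AFF1 (AF4), AFF4, MLLT3 (AF9) and MLLT1 (ENL), which join elongation complexes, and DOT1L is the H3K79 methyltransferase that binds MLLT1 and MLLT3. RNA-seq compared knockdowns of ENL, AFF4 and DOT1L with controls in HEL, a human erythroleukaemia line, with 2 libraries per arm and 12 in all. PRO-seq covered a control and 5 knockdowns in HEL with 1 library each. Peak tables covered the MLL N terminus (MLL-N) in THP1 (monocytic), CCRF-CEM (T lymphoid), HEL and SEM-K2 (B lymphoid) cells, the acetyltransferase p300 in THP1, and FLAG-tagged MLL-AF9 in mouse iMA9 leukaemia cells. MLL-N peaks cannot tell MLL1 from a fusion protein that keeps its N terminus, and the fusion status of the lines was not used here. The labels do not say that RNA-seq replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The 2 controls of the AFF4 set and the 2 ENL knockdown libraries differed more than other pairs, with median absolute log2 differences across genes of 0.274 and 0.230 against 0.064 to 0.082 in the other 4 pairs.

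The targeted transcripts were lower in their own knockdown libraries. MLLT1 fell from 15.7 and 16.1 RPKM in the ENL-set controls to 6.52 and 4.10 RPKM in the ENL knockdown libraries (log2 −1.45, SE 0.20, limma adjusted p = 4.0e-04). AFF4 fell from 8.66 and 7.13 RPKM to 2.02 and 2.06 RPKM after its own knockdown (log2 −1.54, SE 0.11, adjusted p = 2.2e-04; 0.0829 in a fit of that set alone). The entry that joins DOT1L with PLEKHJ1 stood at 10.3 and 10.1 RPKM in controls and 5.47 and 5.64 RPKM in DOT1L knockdown libraries, and its difference did not pass (log2 −0.77, SE 0.24, adjusted p = 0.060). Without control replicate 2 of the AFF4 set, where that entry was highest (14.9 RPKM), it passed (adjusted p = 0.0116), as it did with median-centred libraries (0.0425), with pooled controls (0.0187) and in a fit of its set alone (0.00113). The target check for DOT1L rests on this shared entry. In the control and knockdown libraries of the other sets, MLLT1 ranged from 15.2 to 23.8 RPKM, AFF4 from 9.04 to 12.7 RPKM, and the DOT1L entry from 7.29 to 14.9 RPKM.

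**Figure D1:**
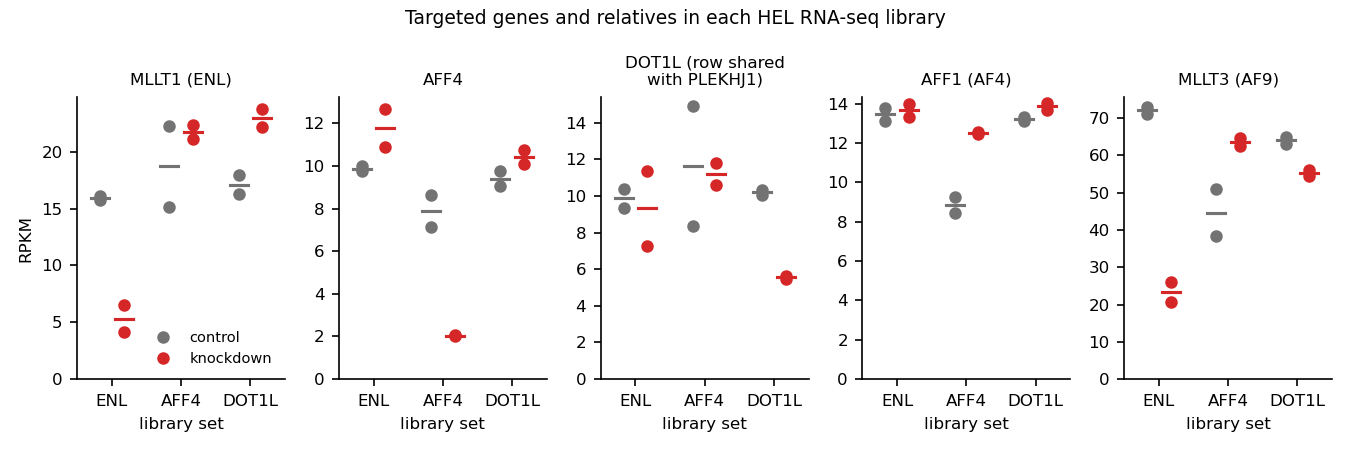
RPKM (vertical axis) of MLLT1, AFF4, the joint DOT1L entry, AFF1 and MLLT3 in each library of the 3 HEL library sets (horizontal axis), with controls in grey, knockdowns in red, points for libraries and bars for the mean of 2. MLLT1 averaged 5.31 RPKM in the ENL knockdown against 15.9 in its controls, and AFF4 averaged 2.04 against 7.90.

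Among the relatives, MLLT3 fell with ENL knockdown from 72.1 ± 1.22 to 23.4 ± 3.77 RPKM (SD, n = 2; log2 −1.59, adjusted p = 3.0e-05), while AFF1 (log2 0.02, adjusted p = 0.85) and AFF4 (log2 0.23, adjusted p = 0.10) did not pass. Without control replicate 2 of the AFF4 set, AFF4 passed in the ENL knockdown (adjusted p = 0.047), as it did with pooled controls (0.0402). With AFF4 knockdown, AFF1 rose from 8.86 ± 0.587 to 12.5 ± 0.0718 RPKM (adjusted p = 0.0059) and MLLT3 from 44.7 ± 9.04 to 63.6 ± 1.46 RPKM (adjusted p = 0.046). Both calls were lost without AFF4 knockdown replicate 1 (adjusted p = 0.065 and 0.22) or replicate 2 (0.059 and 0.19), and that of MLLT3 without control replicate 2 (0.10). Both were also lost in a fit of the AFF4 set alone (0.26 and 0.31) and with pooled controls (0.71 and 0.74), where AFF1 stood at 13.1 to 13.8 RPKM in the controls of the other sets. None of the 4 relatives passed with DOT1L knockdown, where adjusted p ranged from 0.20 for MLLT1 to 0.61 for AFF1, though MLLT1 (log2 0.41, adjusted p = 0.0085) and MLLT3 (log2 −0.21, 0.0078) passed in a fit of the DOT1L set alone.

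Knockdown of ENL changed 5609 of 11439 genes (49.0%), with 3135 higher and 2474 lower, and 3227 by at least 1.5-fold. MLLT3 fell in these libraries about as far as MLLT1 (log2 −1.59 and −1.45). Effects of lower MLLT1 and of lower MLLT3 therefore cannot be told apart here. The genes with the largest falls included SOCS3, a cytokine-induced inhibitor of JAK signalling, which fell 48.3-fold from 81.8 ± 5.60 to 1.69 ± 0.738 RPKM (SD, n = 2), and the embryonic globin HBE1, which fell 16.9-fold from 377 ± 6.62 to 22.3 ± 2.43 RPKM. The platelet integrin ITGB3 fell from 147 ± 2.13 to 9.36 ± 0.677 RPKM. SLC2A3, a glucose transporter, fell from 294 ± 0.716 to 18.6 ± 0.156 RPKM, and MSMO1, an enzyme of sterol synthesis, from 155 ± 11.3 to 9.73 ± 3.13 RPKM. The fetal globin HBG2 fell from 4557 ± 273 to 441 ± 84.2 RPKM, a value that is uncertain because HBG1 is nearly identical. The largest rises included PTAFR, the platelet-activating factor receptor, from 2.18 ± 0.121 to 38.3 ± 5.79 RPKM, and EVI2B from 2.32 ± 0.255 to 37.5 ± 7.30 RPKM. The signalling adaptor SLA rose from 1.04 ± 0.0600 to 17.5 ± 0.395 RPKM, and ALOX5AP, needed for leukotriene synthesis, from 3.51 ± 0.753 to 35.3 ± 0.177 RPKM. C2orf66 and SLC22A20 completed the 6 largest rises, at 9.20 ± 2.15 and 7.43 ± 0.856 RPKM against 0.332 ± 0.186 and 0.191 ± 0.123 RPKM. Adjusted p for these 12 genes was 6.1e-06 or lower.

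Metabolic and stress lists moved down with ENL knockdown. Of 22 genes of cholesterol synthesis and uptake, 19 fell and 0 rose (also 19 adjusted over the list alone; 0 rose in limma at an adjusted threshold), with a median log2 change of −1.65 (camera adjusted p = 1.9e-11; adjusted p = 0.023 with an estimated correlation). INSIG1, a sterol-regulated retention protein, fell from 133 ± 0.385 to 13.5 ± 1.45 RPKM, SCD, a fatty acid desaturase, from 201 ± 1.25 to 37.7 ± 0.207 RPKM, and FDFT1, squalene synthase, from 157 ± 0.813 to 35.8 ± 1.86 RPKM (SD, n = 2). Of 32 glycolysis and hypoxia genes, 26 fell (26 adjusted over the list alone), among them SLC2A3 above and ALDOC, a glycolytic aldolase, from 306 ± 10.2 to 40.8 ± 6.55 RPKM. The list median was −0.82 (adjusted p = 4.1e-11; adjusted p = 0.019 with an estimated correlation). Of 43 unfolded protein and integrated stress response genes, 25 fell and 4 rose (26 and 4 adjusted over the list alone; median −0.47, adjusted p = 1.3e-05; adjusted p = 0.019 with an estimated correlation). They included asparagine synthetase ASNS, from 26 ± 0.322 to 6.12 ± 0.0620 RPKM, the chaperone HSPA5, from 94.1 ± 2.84 to 41.0 ± 1.82 RPKM, and WARS, a tRNA synthetase, from 38.4 ± 0.394 to 10.4 ± 1.33 RPKM. Oxidative phosphorylation genes had 10 of 34 fall and 1 rise (7 and 1 adjusted over the list alone), with COX7B from 148 ± 13.7 to 63.7 ± 7.70 RPKM. Its median log2 change was −0.24 (adjusted p = 0.0070; adjusted p = 0.16 with an estimated correlation, and 0.413 under quantile normalization).

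Lineage and signalling lists also moved with ENL knockdown, though their calls were lost with an estimated correlation. Of 45 erythroid genes, 25 fell and 8 rose (the same numbers adjusted over the list alone; median −0.42, adjusted p = 1.5e-05; adjusted p = 0.39 with an estimated correlation). ALAS2, the erythroid enzyme that starts haem synthesis, fell from 99.1 ± 7.25 to 8.80 ± 0.828 RPKM (SD, n = 2), and CA2, a carbonic anhydrase, from 57.5 ± 0.448 to 7.33 ± 0.269 RPKM. Of 32 megakaryocyte and platelet genes, 18 fell and 6 rose (18 and 6 adjusted over the list alone; median −0.57, adjusted p = 1.3e-04; adjusted p = 0.15 with an estimated correlation). The platelet chemokine PF4 fell from 12 ± 1.11 to 1.57 ± 0.152 RPKM and the ADP receptor P2RY1 from 51.8 ± 0.841 to 15.6 ± 0.556 RPKM. Of 19 JAK-STAT5 response genes, 15 fell and 1 rose (15 and 2 adjusted over the list alone), including the kinases PIM1, from 964 ± 18.3 to 105 ± 12.3 RPKM, and PIM2, from 233 ± 5.44 to 53.7 ± 2.81 RPKM. The median over the list was −0.80 (adjusted p = 2.0e-05; adjusted p = 0.25 with an estimated correlation). Of 24 immediate early genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone; median −0.36, adjusted p = 0.0014; adjusted p = 0.51 with an estimated correlation). The phosphatase DUSP5 fell from 13.4 ± 0.0996 to 2.98 ± 0.202 RPKM, and PPP1R15A, from 145 ± 4.11 to 31.5 ± 7.05 RPKM.

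Cell cycle lists parted in the ENL knockdown. Of 34 G2/M genes, 27 fell and 1 rose (27 and 1 adjusted over the list alone), with the securin PTTG1 falling from 90.9 ± 4.11 to 31.7 ± 2.79 RPKM (SD, n = 2) and the kinase NEK2 from 32.1 ± 0.607 to 12.5 ± 0.323 RPKM. Over the list, the median was −0.70 (adjusted p = 1.4e-08; adjusted p = 0.16 with an estimated correlation). Of 41 S phase genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone). GINS2, part of the replicative helicase, rose from 10.5 ± 1.77 to 21.5 ± 1.38 RPKM and the entry joining the replication clamp PCNA with its antisense gene from 48.7 ± 1.30 to 88.2 ± 2.24 RPKM. The median log2 change was 0.46 (adjusted p = 5.0e-04; adjusted p = 0.034 with an estimated correlation). The S phase call was lost, and the direction of the test turned, when all 6 controls were pooled without library set (adjusted p = 0.782), where GINS2 (0.36) and the PCNA entry (0.56) also lost their calls.

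The other 16 lists were not called in the ENL knockdown. Canonical MLL fusion targets had 5 of 19 genes rise and 4 fall (6 and 4 adjusted over the list alone; adjusted p = 0.93), and HOX cluster genes had 4 of 14 rise and 4 fall (adjusted p = 0.63). The super elongation complex and P-TEFb (3 rose and 4 fell of 13; adjusted p = 0.81) had a median of 0.14 and a mean of −0.12, so median and test differed in sign. They also did for ribosomal protein genes (4 rose and 5 fell of 49; adjusted p = 0.91) and histone genes (5 rose and 4 fell of 16; adjusted p = 0.91). P-TEFb inhibition and pausing factors (1 rose and 3 fell of 8) had adjusted p = 0.49, the PAF1 complex (3 rose of 6) 0.39, the MLL complex (3 rose and 2 fell of 9) 0.60, and RNA polymerase II subunits (1 rose and 2 fell of 6) 0.62. NF-kB genes (1 rose and 7 fell of 14) had adjusted p = 0.058, heat shock genes (8 rose and 2 fell of 13) 0.20, p53 targets (3 rose and 6 fell of 18) 0.30, interferon genes (15 rose and 8 fell of 38) 0.62, and MYC target and nucleolar genes (12 rose and 4 fell of 31) 0.34. Markers of other blood lineages were not called by camera, with 5 rising and 3 falling of 13 myeloid genes (adjusted p = 0.92) and 3 rising of 6 lymphoid genes (adjusted p = 0.30, mean log2 0.70). The NF-kB list passed, lower, without a filter (0.0138), with a minimum of 5 RPKM (0.0203), under quantile normalization (0.0257), without ENL knockdown replicate 1 (0.0321) and without control replicate 2 of the AFF4 set (0.0489). HOX genes passed with a minimum of 5 RPKM (0.0306) and MYC targets under quantile normalization (0.0434). By fry, which does not compare a list with other genes, the lymphoid list moved up (adjusted p = 0.0048), and the PAF1, MLL complex, HOX, heat shock, interferon, NF-kB, p53 and MYC lists passed too, with adjusted p of 0.0082 or lower.

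Knockdown of AFF4 changed 1248 genes, with 691 higher and 557 lower, and 471 by at least 1.5-fold. Metallothioneins, which bind zinc and copper, led the falls: MT1X fell 7.77-fold from 80.7 ± 16.9 to 10.4 ± 0.963 RPKM (SD, n = 2; adjusted p = 3.6e-05). MT1G fell from 21 ± 2.97 to 2.13 ± 0.319 RPKM, MT2A from 456 ± 151 to 66.1 ± 5.82 RPKM and MT1E from 21.9 ± 1.61 to 5.25 ± 0.412 RPKM, though near-identical copies can share their reads. TPM4, a tropomyosin, fell 3.47-fold from 132 ± 13.5 to 38.0 ± 0.465 RPKM (adjusted p = 3.6e-05). CPA3, a mast cell protease, rose 3.31-fold from 20.5 ± 3.74 to 68.0 ± 1.34 RPKM (adjusted p = 3.1e-04), the lymphoid surface protein CD2 from 3.51 ± 1.2 to 12.4 ± 0.0869 RPKM, and PSKH2 from 1.62 ± 0.285 to 8.48 ± 0.531 RPKM. The other named rises were CCDC173, STMN3 and SPINK4, by 4.21-, 5.35- and 4.01-fold. MIR1281 was listed at 0 in both knockdown libraries and at 5.37 ± 1.77 RPKM in controls (adjusted p = 0.023). This call was lost with a pseudocount of 0.1 (0.051), with pooled controls (0.28), and without control replicate 2 (0.065), knockdown replicate 1 (0.128) or knockdown replicate 2 (0.131).

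The AFF4 count moved with the libraries used. It was 303 without knockdown replicate 1, 298 without knockdown replicate 2, and 0 in a limma fit of the 4 AFF4 libraries alone, where 1536 genes had an unadjusted p under 0.05. Of 51 named genes, 49 were called in the main fit, and all 49 lost their call in the fit of the set alone, where no gene passed. With pooled controls 15 lost it and 3 turned. With the replicate number as a block, 415 genes passed and 19 of the named genes lost their call. AFF1 (limma adjusted p = 0.057), MLLT3 (0.088) and MYC (0.063) were among these. Those lost with pooled controls included CPA3 (adjusted p = 0.103), PSAT1 (0.425), CXCL8 (0.307), BRCA2 (0.073), ATF3 (0.0659) and RPL27 (0.0524). Without knockdown replicate 1 or 2 the calls of MYC (0.0721 and 0.103), ODC1 (0.125 and 0.0823), RPL27 (0.115 and 0.0832), NFKBIA (0.0834 and 0.0986) and NFKB1 (0.118 and 0.168) were lost. So were those of BRCA2 (0.197 and 0.214), RFC5 (0.159 and 0.293) and SPINK4 (0.0768 and 0.0901), and that of CXCL8 without replicate 2 (0.0784). The share of higher genes was 55.4% as tested and 43.5% (431 higher, 559 lower) with median-centred libraries.

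Proliferation, metabolic and stress lists moved down with AFF4 knockdown. Of 34 G2/M genes, 19 fell and 0 rose in limma (28 fell adjusted over the list alone), including the proliferation marker MKI67, from 39.5 ± 1.31 to 25.7 ± 0.0575 RPKM (SD, n = 2), and the kinesin KIF2C, from 78.6 ± 2.83 to 48.4 ± 1.10 RPKM. The list median was −0.44 (adjusted p = 3.1e-18; adjusted p = 0.065 with an estimated correlation). Of 43 unfolded protein and integrated stress response genes, 8 fell (14 adjusted over the list alone), among them the serine synthesis enzyme PSAT1, from 31.5 ± 1.01 to 15.8 ± 0.704 RPKM. The list passed with either correlation (median −0.20, adjusted p = 1.6e-06; adjusted p = 0.021 with an estimated correlation), but not with pooled controls (0.359). Of 32 glycolysis and hypoxia genes, 13 fell and 1 rose (18 and 4 adjusted over the list alone), with SLC2A3 falling from 104 ± 6.43 to 54.0 ± 0.919 RPKM. Its median log2 change was −0.41 (adjusted p = 2.6e-06; adjusted p = 0.065 with an estimated correlation). Of 22 cholesterol genes, 8 fell (11 adjusted over the list alone), with INSIG1 falling from 69.1 ± 5.83 to 33.7 ± 0.762 RPKM. The median over the list was −0.22 (adjusted p = 1.4e-05; adjusted p = 0.092 with an estimated correlation). Of 41 S phase genes, 3 fell (1 adjusted over the list alone), including BRCA2 and RFC5, whose calls were lost without control replicate 1 (adjusted p = 0.128 and 0.113). Over the list, the median was −0.11 (adjusted p = 0.018; adjusted p = 0.098 with an estimated correlation). This call was lost without control replicate 1 (adjusted p = 0.118), and its direction turned with pooled controls (0.17).

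Signalling lists moved down as well. Of 24 immediate early genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), including the transcription factors ATF3, from 4.20 ± 0.310 to 1.0 ± 0.191 RPKM, and EGR1, from 45.7 ± 6.14 to 21.8 ± 1.38 RPKM (SD, n = 2). The median log2 change was −0.25 (adjusted p = 0.0020; adjusted p = 0.47 with an estimated correlation). EGR1 averaged 0.381 RPKM in the ENL-set controls and 2.96 RPKM in the DOT1L-set controls, and its log2 change was 1.85, without passing, against pooled controls. Of 14 NF-kB genes, 3 fell (3 adjusted over the list alone), the chemokine CXCL8, from 2.99 ± 0.845 to 0.846 ± 0.237 RPKM, and the NF-kB components NFKBIA and NFKB1 (for NFKB1, adjusted p = 0.0526 without control replicate 1). The list median was −0.30 (adjusted p = 3.7e-04; adjusted p = 0.092 with an estimated correlation). Of 19 JAK-STAT5 response genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with PIM1 falling from 574 ± 78.0 to 321 ± 7.81 RPKM and PIM2 from 189 ± 12.9 to 123 ± 2.52 RPKM. Its median log2 change was −0.19 (adjusted p = 0.0060; adjusted p = 0.43 with an estimated correlation). Without control replicate 2 the immediate early (adjusted p = 0.522) and JAK-STAT5 (0.175) calls were lost, and both were lost with pooled controls (0.258 and 0.101). The immediate early call was also lost with a minimum of 5 RPKM (0.0845) and by fry (0.0839).

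Lists that moved up with AFF4 knockdown did so by small steps, and all lost their calls with an estimated correlation. Of 19 canonical MLL fusion targets, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with LMO2, a haematopoietic transcription cofactor, rising from 60.9 ± 1.55 to 101 ± 4.37 RPKM (SD, n = 2) and MYC from 188 ± 6.51 to 243 ± 5.61 RPKM. The median over the list was 0.14 (adjusted p = 0.041; adjusted p = 0.47 with an estimated correlation). Of 45 erythroid genes, 9 rose and 2 fell (11 and 3 adjusted over the list alone), including LMO2, which is on both lists, ferrochelatase FECH, from 10.0 ± 0.428 to 17 ± 0.331 RPKM, and glycophorin GYPB, from 65.3 ± 3.95 to 102 ± 3.76 RPKM. Over the list, the median was 0.17 (adjusted p = 0.028; adjusted p = 0.54 with an estimated correlation). Of 49 ribosomal protein genes, 4 rose (3 adjusted over the list alone), with RPL27 from 1110 ± 68.2 to 1386 ± 28.4 RPKM. The median log2 change was 0.15 (adjusted p = 0.0020; adjusted p = 0.43 with an estimated correlation). Of 31 MYC target and nucleolar genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with the polyamine enzyme ODC1 rising from 186 ± 7.95 to 229.99 ± 5.93 RPKM. The list median was 0.17 (adjusted p = 0.018; adjusted p = 0.14 with an estimated correlation). Without control replicate 1 the erythroid (adjusted p = 0.791) and MYC target (0.0942) calls were lost, and the fusion target call was lost without control replicate 2 (0.394) or knockdown replicate 1 (0.0507). With pooled controls the erythroid (0.124) and ribosomal (0.107) calls were lost, and the direction of the fusion target test turned (0.723). The fusion target call was also lost with median-centred libraries (0.0556) and in a fit of the AFF4 set alone (0.0572), and the erythroid call in the fit of the set alone (0.0565) and by fry (0.0855).

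The remaining 14 lists were not called in the AFF4 knockdown. The PAF1 complex had 2 of 6 genes rise (adjusted p = 0.071), p53 targets had 3 of 18 fall (0.079), megakaryocyte and platelet genes had 5 rise and 7 fall of 32 (0.15), and interferon genes had 4 rise and 5 fall of 38 (0.15). Histone genes had 1 of 16 fall (adjusted p = 0.15), lymphoid genes 1 rise and 1 fall of 6 (0.16), myeloid genes 2 of 13 rise (0.43), and the super elongation complex and P-TEFb 2 rise and 1 fall of 13 (0.48). No member passed in limma for heat shock genes (adjusted p = 0.35), RNA polymerase II subunits (0.43), HOX genes (0.75), P-TEFb inhibition and pausing factors (0.81) or the MLL complex (0.95). Oxidative phosphorylation genes had 2 of 34 rise (0.95). Median, mean and test differed in sign for the MLL complex, HOX and oxidative phosphorylation lists. The PAF1 list passed without a filter (0.027) and without control replicate 1 (0.0174). With pooled controls the heat shock (0.0402), megakaryocyte (0.0055), interferon (3.0e-04) and histone (0.0224) lists passed, and by fry the PAF1 (0.0301), myeloid (0.0417) and p53 (2.2e-05) lists.

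Knockdown of DOT1L changed 1974 genes, with 885 higher and 1089 lower, and 808 by at least 1.5-fold. A fit of the DOT1L set alone called 5094 genes. Red cell genes led the rises: AHSP, the chaperone of alpha globin, rose from 0.0776 ± 0.110 to 6.55 ± 1.02 RPKM (SD, n = 2; adjusted p = 2.1e-05). The embryonic globin HBZ rose from 2.85 ± 0.678 to 20.9 ± 1.87 RPKM (adjusted p = 0.0028). The alpha globin HBA2, nearly identical to HBA1 and so uncertain, rose from 46.0 ± 1.29 to 272 ± 6.96 RPKM (adjusted p = 3.5e-04). C17orf99, LOC101928353 and ESPN completed the 6 largest rises, at 6.38 ± 0.0998, 8.81 ± 2.65 and 5.14 ± 0.154 RPKM against 0.144 ± 0.204, 1.05 ± 0.336 and 0.409 ± 0.0438 RPKM. The largest falls included PRG2, an eosinophil granule protein, from 128 ± 0.156 to 33.9 ± 0.118 RPKM, and the transglutaminase TGM5, from 19.7 ± 0.672 to 4.02 ± 0.199 RPKM. RGS18, a regulator of G protein signalling in platelets, fell from 129.6 ± 1.65 to 37.8 ± 0.919 RPKM, the ligand ANGPT1 from 30.8 ± 1.15 to 8.57 ± 0.419 RPKM, and SEMA3C from 6.08 ± 0.113 to 0.994 ± 0.0724 RPKM. MIR4737 also fell (adjusted p = 0.011), a call lost without control replicate 1 (0.093), knockdown replicate 1 (0.071) or knockdown replicate 2 (0.069). The DOT1L count fell to 817 and 813 without control replicates 1 and 2 of the set, and to 784 and 816 without knockdown replicates 1 and 2.

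The lineage lists parted with DOT1L knockdown. Of 45 erythroid genes, 21 rose and 2 fell (23 and 2 adjusted over the list alone), including GYPB, from 57.5 ± 2.75 to 183 ± 8.69 RPKM (SD, n = 2). The median log2 change of the list was 0.28 (adjusted p = 1.1e-06; adjusted p = 0.41 with an estimated correlation). Of 32 megakaryocyte and platelet genes, 16 fell and 4 rose (18 and 6 adjusted over the list alone), including ITGB3, from 160.2 ± 0.104 to 78.5 ± 1.80 RPKM, the adhesion receptor SELP, from 38.1 ± 0.820 to 17.9 ± 0.214 RPKM, and PLEK, from 591 ± 9.24 to 286 ± 2.59 RPKM. The median over the list was −0.43 (adjusted p = 9.0e-05; adjusted p = 0.37 with an estimated correlation, and 0.22 with pooled controls). Of 19 canonical MLL fusion targets, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with the transcription factors MYB falling from 52.9 ± 0.109 to 29.4 ± 1.10 RPKM and MEIS1 from 9.73 ± 0.671 to 5.36 ± 0.267 RPKM (for MEIS1, adjusted p = 0.0885 with pooled controls). Over the list, the median was −0.17 (adjusted p = 0.017; adjusted p = 0.47 with an estimated correlation, and 0.424 with pooled controls).

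Of 32 glycolysis and hypoxia genes, 10 rose and 2 fell with DOT1L knockdown (11 and 3 adjusted over the list alone), including the hypoxia-induced NDRG1, from 11.6 ± 0.212 to 30.1 ± 1.21 RPKM (SD, n = 2), and PGK1, phosphoglycerate kinase, from 282 ± 7.85 to 435 ± 0.357 RPKM. The median log2 change was 0.31 (adjusted p = 0.0064; adjusted p = 0.37 with an estimated correlation). Of 49 ribosomal protein genes, 6 rose (3 adjusted over the list alone), with RPS12 from 991 ± 0.791 to 1451 ± 10.7 RPKM. The list median was 0.18 (adjusted p = 4.2e-04; adjusted p = 0.41 with an estimated correlation). The ribosomal call was lost under quantile normalization (0.562) and with pooled controls (0.518).

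The other 21 lists were not called in the DOT1L knockdown. Unfolded protein and integrated stress response genes had 10 of 43 fall (adjusted p = 0.093), cholesterol genes 6 of 22 fall (0.093) and NF-kB genes 4 of 14 fall (0.093). Oxidative phosphorylation genes had 2 rise and 1 fall of 34 (adjusted p = 0.11), G2/M genes 5 rise and 1 fall of 34 (0.18), JAK-STAT5 response genes 1 rise and 4 fall of 19 (0.25), interferon genes 5 rise and 4 fall of 38 (0.25), and histone genes 3 of 16 rise (0.34). Adjusted p was 0.61 for immediate early genes (4 rose and 3 fell of 24), 0.61 for heat shock genes (2 rose of 13), 0.74 for S phase genes (1 rose and 3 fell of 41), 0.74 for HOX genes (1 fell of 14), 0.76 for lymphoid genes (1 rose of 6) and 0.76 for RNA polymerase II subunits, of which none passed in limma. Among elongation lists, adjusted p was 0.77 for P-TEFb inhibition and pausing factors (1 fell of 8), 0.77 for the PAF1 complex (1 rose of 6) and 0.90 for the super elongation complex and P-TEFb (1 rose and 2 fell of 13). Myeloid genes (2 rose and 1 fell of 13) had adjusted p = 0.90, p53 targets (1 rose and 3 fell of 18) 0.92, the MLL complex (none passed in limma) 0.92, and MYC targets (4 rose and 4 fell of 31) 0.94. Median, mean and test differed in sign for the super elongation, MLL complex, myeloid, p53 and MYC lists. With pooled controls the stress response (2.1e-05), G2/M (7.0e-05) and histone (0.0143) lists passed, and without a filter the stress response (0.0192), NF-kB (0.0201) and cholesterol (0.0217) lists. Oxidative phosphorylation genes passed in a fit of the set alone (0.0161) and by fry (0.0099), as did NF-kB (0.0017) and stress response genes (0.0043) by fry, where p53 targets turned up (0.00166).

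**Figure D2:**
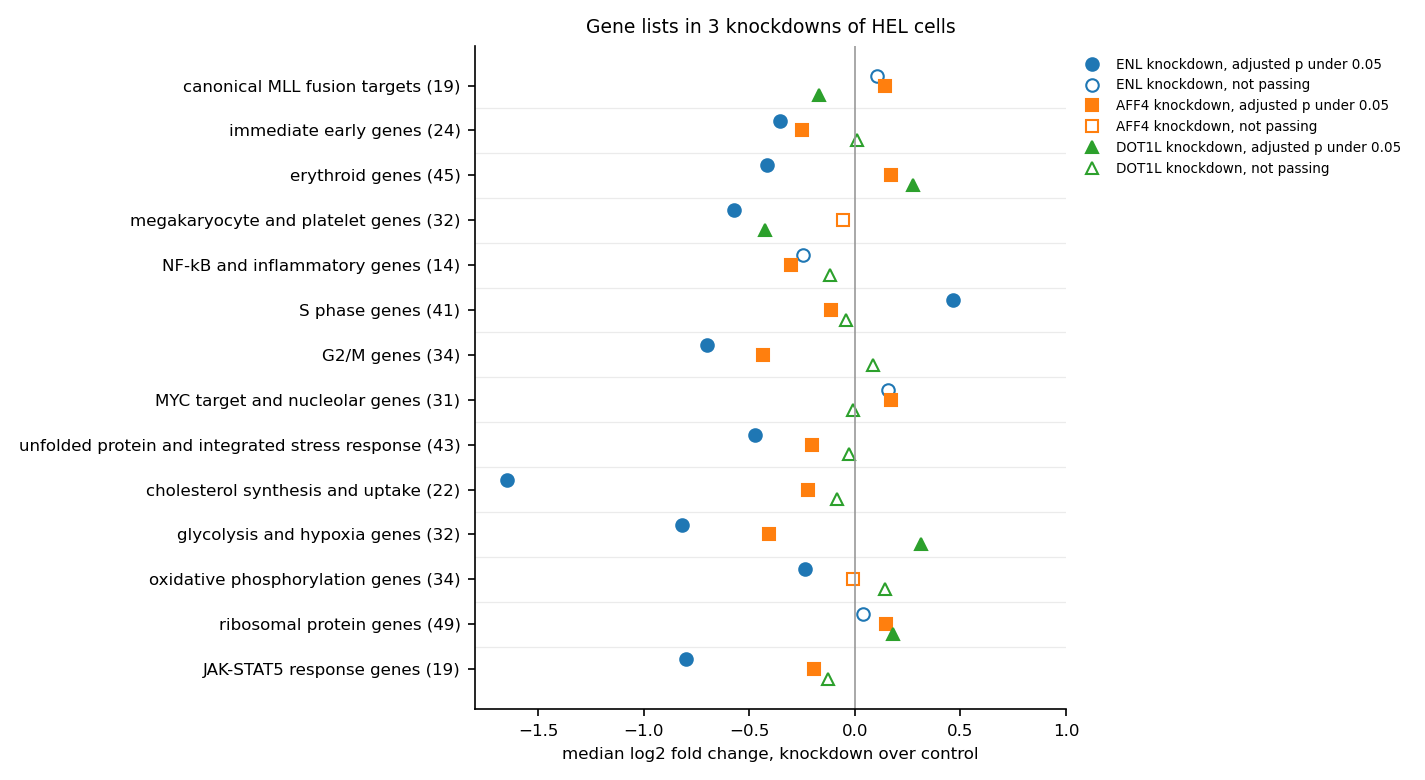
Median log2 fold change of knockdown over control (horizontal axis) for the gene lists called in at least 1 knockdown (vertical axis, kept members in parentheses), with filled symbols for lists with camera adjusted p under 0.05 and open symbols for the rest. Erythroid genes lay at −0.42 with ENL, 0.17 with AFF4 and 0.28 with DOT1L knockdown, and cholesterol genes at −1.65, −0.22 and −0.09.

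Tests of the difference between knockdowns used a limma contrast of the effects, each against its own controls. Erythroid genes moved lower with ENL than with DOT1L knockdown, with 31 of 45 lower and 2 higher (median difference −1.29, camera adjusted p = 2.5e-12; adjusted p = 0.16 with an estimated correlation). Glycolysis and hypoxia genes differed in the same direction, with 26 of 32 lower (median difference −1.25, adjusted p = 7.0e-15; adjusted p = 0.014 with an estimated correlation). Cholesterol genes lay lower with ENL than with AFF4 (16 of 22 lower; median difference −1.36, adjusted p = 1.1e-11; adjusted p = 0.023 with an estimated correlation) and than with DOT1L knockdown (17 lower; −1.56, adjusted p = 2.1e-12; adjusted p = 0.025 with an estimated correlation). S phase genes lay higher with ENL than with AFF4 (21 of 41 higher; median difference 0.44, adjusted p = 2.7e-06; adjusted p = 0.023 with an estimated correlation), but with pooled controls the call was lost and its direction turned (median difference −0.33, adjusted p = 0.121). Canonical MLL fusion targets lay higher with AFF4 than with DOT1L knockdown (8 of 19 higher, 1 lower; median difference 0.38, adjusted p = 3.3e-04; adjusted p = 0.35 with an estimated correlation, and 0.703 with pooled controls), and G2/M genes lower (15 of 34 lower; −0.50, adjusted p = 2.2e-12; adjusted p = 0.23 with an estimated correlation). Over all genes, the effects of ENL and AFF4 knockdown differed at 3289 genes, those of ENL and DOT1L at 3887, and those of AFF4 and DOT1L at 1365.

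The called genes also overlapped. The comparisons share each gene's variance estimate, so low-variance genes are more readily called in each of them. Excess over independent lists alone therefore cannot measure a shared response. ENL and AFF4 knockdown shared 360 higher and 354 lower genes, where independent lists would share 189 and 120 (Fisher's exact p = 1.5e-45 and 6.9e-107 across genes, which are not independent replicates). Opposite directions held 60 genes higher with ENL and lower with AFF4 and 132 the other way, where independent lists would share 153 and 149. ENL and DOT1L knockdown shared 393 higher and 468 lower genes (243 and 236 for independent lists), and in opposite directions 208 and 187 (298 and 191). AFF4 and DOT1L shared 165 and 147 (53.5 and 53), and in opposite directions 123 and 64 (65.8 and 43.1; Fisher's exact p = 2.8e-12 and 0.0014). Pearson's r of log2 fold changes across genes was 0.349 for ENL with AFF4, 0.204 for ENL with DOT1L and 0.122 for AFF4 with DOT1L (Spearman's rho 0.340, 0.215 and 0.140). These comparisons share no control libraries. When all controls were pooled, r was 0.282, 0.148 and 0.163 against 0.251, 0.249 and 0.249 for simulated unchanged groups, and the covariance was 0.0670, 0.0313 and 0.0228 against 0.00897, 0.00892 and 0.00893.

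PRO-seq profiles around start sites asked where polymerase stood after each knockdown. With AFF4 knockdown the sense maximum was 0.0841 per bp and start site at +60 bp, against 0.0530 at +80 bp in the control (158%), and with ENL knockdown it was 0.0690 at +70 bp (130%). It was 0.0465 at +80 bp with DOT1L (87.6%), 0.0495 at +80 bp with AF9 (93.3%) and 0.0421 at +90 bp with AF4 knockdown (79.3%). The antisense maximum was 0.0351 with AFF4 and 0.0303 with ENL knockdown, both at −140 bp, against 0.0212 at −160 bp in the control. The ratio of proximal to downstream signal was 3.31 in the control, 4.23 with AFF4, 3.67 with ENL, 3.55 with AF9, 3.43 with AF4 and 2.83 with DOT1L knockdown. Downstream signal lay between 0.00981 (AF4) and 0.0132 (AFF4), against 0.0122 in the control. Each condition had 1 library, so no difference has a replicate check, depth and normalization are unknown, and the ENL ratio turned below that of the control with a proximal window to +500 bp (log2 −0.0090 against 0.15).

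**Figure D3:**
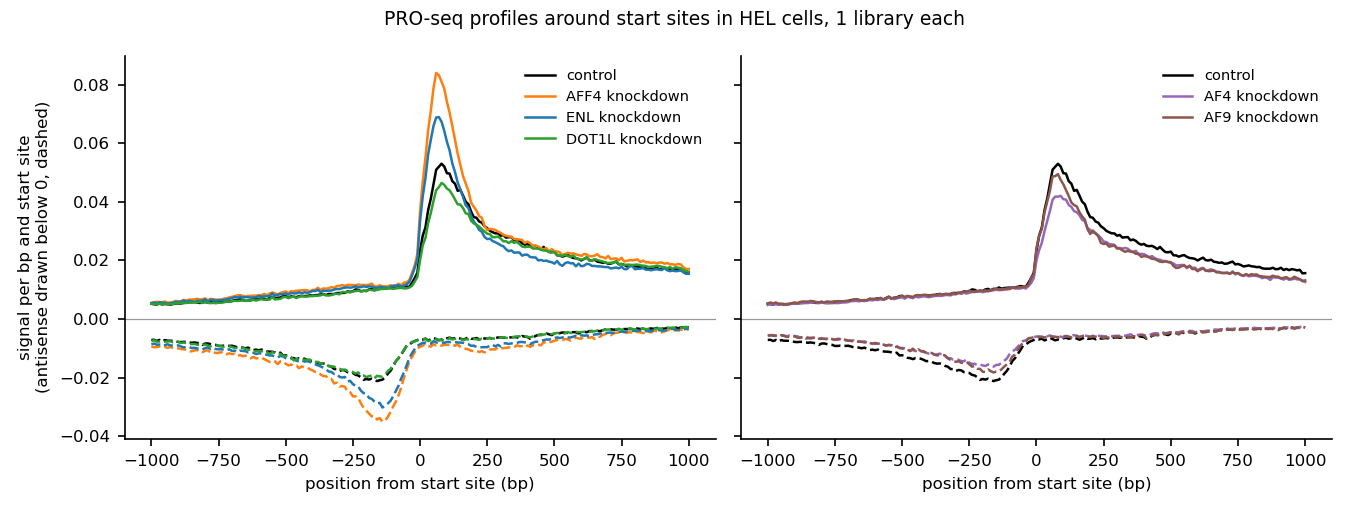
PRO-seq signal per bp and start site (vertical axis; antisense drawn below 0, dashed) against position from the start site in bp (horizontal axis) in the HEL control and 5 knockdowns, 1 library per line. The sense maximum reaches 0.0841 with AFF4 and 0.0690 with ENL knockdown against 0.0530 in the control.

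MLL-N peak tables held 9373 peaks in THP1, 8709 in CCRF-CEM, 866 in HEL and 15616 in SEM-K2, with median widths of 256, 265, 169 and 242 bp. Of the HEL peaks, 80.0% (95% Wilson interval 77.2% to 82.6%) overlapped a THP1 peak, 77.1% (74.2% to 79.8%) a SEM-K2 peak and 74.8% (71.8% to 77.6%) a CCRF-CEM peak, and 585 of 866 overlapped all of these tables. Of the CCRF-CEM peaks, 72.5% (71.5% to 73.4%) overlapped a SEM-K2 peak and 57.4% (56.3% to 58.4%) a THP1 peak, and 63.5% (62.5% to 64.5%) of the THP1 peaks overlapped a SEM-K2 peak. The highest-scoring peaks, by the authors' own score, lay at chromosome 1, 40973685 to 40975484 (hg19) in THP1, chromosome 5, 96142925 to 96144407 in CCRF-CEM, chromosome 9, 4740536 to 4741313 in HEL, and chromosome 1, 161014468 to 161015064 in SEM-K2. Whether they lie in genes was not determined, since no hg19 annotation was used here. The THP1 and HEL ones lay in the dense intervals of chromosomes 1 and 9 described below, where a copy gain stays a hypothesis. Each table came from 1 library called by itself, so peak numbers can follow depth or enrichment, and the HEL share in THP1 was 25.4% when each peak had to cover 50% of the other.

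Of the 9373 THP1 MLL-N peaks, 3370 (36.0%, 35.0% to 36.9%) overlapped 1 of 31210 p300 peaks. Circular shifts of the p300 peaks along each chromosome gave 60.6 ± 9.13 overlapping peaks (SD over 1000 shifts, chosen after the tables were seen), and none reached the observed number (permutation p = 0.001, the smallest they can give). Shifted peaks also land in regions without promoters, so the 55.6-fold excess covers any shared preference for active chromatin. In higher-scoring peaks of both tables the overlap was 19.6%. With all peaks, MLL-N peaks of the other lines overlapped the THP1 p300 peaks at 33.2% (SEM-K2), 32.1% (HEL) and 25.6% (CCRF-CEM). Much of the overlap was thus not particular to THP1. The mouse iMA9 table held 9019 MLL-AF9 peaks with a median width of 243 bp and a longest peak of 7588 bp.

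**Figure D4:**
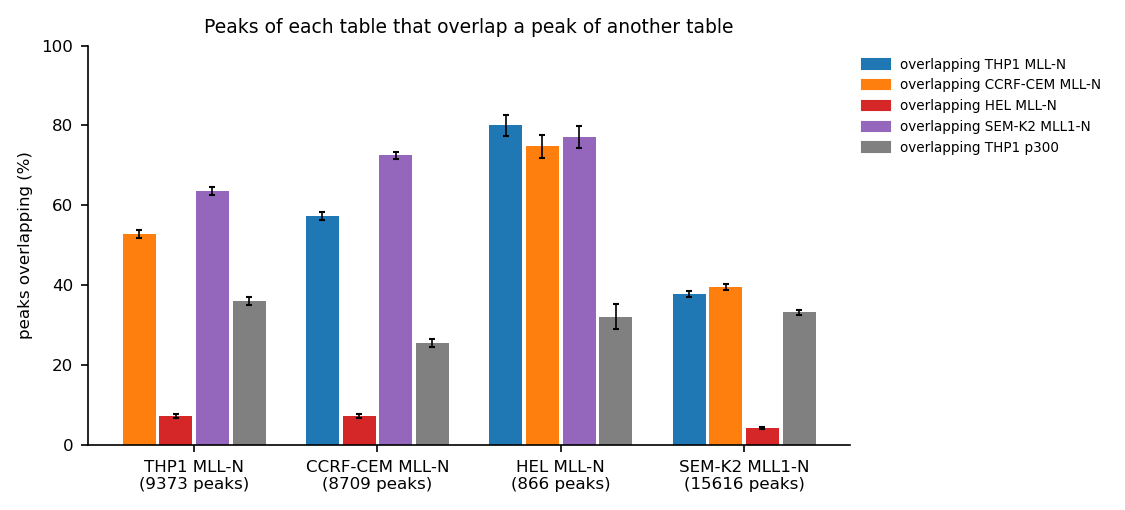
Percent of the peaks of each MLL-N table (groups on the horizontal axis) that overlap a peak of another table by at least 1 bp (vertical axis), with bar colours for the other table and 95% Wilson intervals as error bars. HEL peaks overlap THP1, CCRF-CEM and SEM-K2 MLL-N peaks at 80.0%, 74.8% and 77.1%.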

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

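Among the tests in this part, the tests of depth and of an exchange with another set were chosen only after the result was seen. In the 6 control libraries, 108 measures were examined for a library far from the others, and 6 stood out (5.56%, where the nominal 5% takes the libraries as exchangeable). The value given for each is the gap to the nearest library divided by the whole range. The controls come as pairs by set, so this gap cannot show a shift that both controls of a set share. Control replicate 2 of the AFF4 set was highest for SOCS3 (0.664; 111 RPKM against 73.0 to 85.8), for HBZ (0.685; 8.63 RPKM against 1.41 to 3.68) and for the joint DOT1L entry (0.689; 14.9 RPKM against 8.38 to 10.4). Control replicate 1 of that set was highest for UQCRC2 (0.856; 128 RPKM against 109 to 112) and for relative depth (0.723; 1 against 0.692 to 0.777). Control replicate 1 of the DOT1L set was lowest for SPINK4 (0.664; 0.427 RPKM against 2.05 to 2.87).

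The 2 controls of the AFF4 set differed by a median absolute log2 of 0.274 across genes, more than the other control pairs. Lower depth was argued against, since among genes with at least 20 RPKM the pair still differed 6.46 times as much as the DOT1L-set controls. That replicate 2 was a control of another analysed set under the wrong name was argued against too, since the nearest of those lay farther from it (0.297) than its own partner did, by 0.0239 (0.0151 to 0.0347 over 200 resamples of genes). Replicate 1 lay nearer to a DOT1L-set control (0.209) than to its partner, but an exchange was argued against, since each of the 4 controls of the other sets lay nearer to its own partner, by 0.142 or more (0.137 to 0.148 over the resamples), while a swap with the AF4 and AF9 sets, not analysed here, stays open. The difference between these controls correlated across genes with that between the 2 ENL knockdown libraries (r = 0.713), so an axis of library preparation or culture shared by the sets may lie behind both, and no biological explanation was tested.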

How the results depend on the processing

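Among the tests in this part, those without control replicate 2 of the AFF4 set for the other knockdowns, the crossed replicate block, list differences with pooled controls, and all tests of lists and targeted genes except those of the pseudocount, pooled controls, estimated correlation and fry were chosen only after the data were seen. Single named genes kept their side of the threshold, with no reversal counted, in 1527 of 1707 values. Of the rest, 173 no longer passed, 4 newly passed and 3 reversed. Single lists kept it in 1160 of 1245, with 46 no longer passing, 35 newly passing and 4 reversed. A turn of direction counted as reversed only where at least 1 of the 2 settings passed, so values passing in neither may have turned. The 3 differences between knockdowns stayed within 1.5 times with pooled controls. Where a value below changed, the cause was not tested, but some changes follow in part from construction. A fold minimum lowers a count. Leaving out a library of an arm widens the standard error of its comparison at a given variance. A fit of a set alone uses only the spread of that set. Depth of the RPKM and PRO-seq values is unknown, so neither can show whether low values fall short of detection.

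A minimum of 1.5-fold left 3227 genes for ENL, 471 for AFF4 and 808 for DOT1L. Fits of a set alone called 0 genes for AFF4 in limma (1536 at an unadjusted p under 0.05; AFF4 itself −1.54, adjusted p = 0.0829) and 5094 for DOT1L. The joint fit applies a common variance per gene to all sets, though their spread was unequal. The SD within arms was 0.302 in the AFF4-set controls and 0.127 in the AFF4 knockdown. It was 0.144 in the DOT1L-set controls and 0.145 in the DOT1L knockdown. Leaving out libraries gave 4086 to 6584 genes for ENL, 298 to 1716 for AFF4 and 784 to 2944 for DOT1L, and 10 to 11, 9 to 12 and 5 to 5 lists. The targeted genes then ranged from −1.73 to −1.17 (MLLT1), −1.67 to −1.42 (AFF4) and −0.79 to −0.75 (the DOT1L entry), where a lone library is assumed to vary like the others. The AFF4 count was 303 and 298 without knockdown replicates 1 and 2, and that of DOT1L 817 and 813 without its control replicates 1 and 2, and 784 and 816 without its knockdown replicates. Of 51 named genes in the AFF4 knockdown, 22 lost their call without knockdown replicate 1 and 23 without replicate 2. The DOT1L entry passed with median-centred libraries (−0.77, adjusted p = 0.0425), pooled controls (−0.80, 0.0187), its set alone (−0.77, 0.00113) and without control replicate 2 of the AFF4 set (0.0116).

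An estimated correlation left 4 lists for ENL, 1 for AFF4 and 0 for DOT1L, where camera called 10, 12 and 5. By fry, which does not compare a list with other genes, 19, 13 and 9 lists moved, and p53 targets turned up with DOT1L knockdown (0.00166). Without a filter 8 lists were called for DOT1L. With pooled controls S phase genes turned in the ENL (0.782) and AFF4 (0.17) knockdowns, as did canonical MLL fusion targets in the AFF4 knockdown (0.723), EGR1 (log2 1.85), RFC5 (0.11) and TFRC (−0.14), none passing. Of 78 list differences between knockdowns, 57 kept their side of the threshold with pooled controls, 8 newly passed, 5 no longer passed and 8 reversed. Not counted as reversed were turns among lists that passed in neither setting, such as canonical MLL fusion targets for ENL minus AFF4 (camera adjusted p = 0.43 and 0.80). The reversed ones were ENL minus AFF4 for S phase (0.121), heat shock (0.0235) and MYC target genes (0.0144), ENL minus DOT1L for S phase (0.853) and ribosomal protein genes (0.488), and AFF4 minus DOT1L for megakaryocyte (0.351), interferon (0.00423) and stress response genes (0.0107).

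With the replicate number as a replicate block, 5076 genes passed for ENL, 415 for AFF4 and 1113 for DOT1L, and canonical MLL fusion targets with AFF4 knockdown had adjusted p = 0.0581. Same-numbered deviations correlated across genes at −0.27 in the ENL set, 0.32 in the AFF4 set and −0.02 in the DOT1L set. With 2 libraries per arm, these values cannot tell whether the numbers pair the libraries. A crossed replicate block for the ENL set gave 5872.

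The PRO-seq log2 ratio of proximal to downstream signal over control was, with proximal windows to +100 and +500 and a downstream window from +500, 0.014, 0.068 and 0.031 for AF4, 0.18, 0.061 and 0.11 for AF9, 0.59, 0.20 and 0.35 for AFF4, −0.26, −0.19 and −0.21 for DOT1L, and 0.38, −0.0090 and 0.22 for ENL. Divided by the profile's own mean, the proximal level turned for AF9 (0.015) and the downstream level for AFF4 (−0.091). Downstream signal for ENL turned from +500 (−0.0011).

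Peak overlaps with the higher-scoring 50% of peaks, with overlap over 50% of each length, and with centres within 1 kb were 19.6%, 14.2% and 46.4% for THP1 MLL-N in p300, 55.1%, 40.4% and 72.0% for THP1 in SEM-K2, 50.6%, 36.3% and 65.0% for CCRF-CEM in THP1, and 68.0%, 47.5% and 80.7% for CCRF-CEM in SEM-K2. By length and by centres, HEL overlaps were 25.4% and 83.1% in THP1 and 22.1% and 82.7% in SEM-K2, and 19.98% by length in CCRF-CEM. The higher-scoring iMA9 peaks numbered 4510. Alternatives that need genes at peaks were not run.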

Other observations

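Among the tests in this part, that of high control libraries in the AFF4 set was chosen only after the result was seen. Genes called in all 3 knockdowns numbered 98 higher and 114 lower, where independent lists would share 14.7 and 11.5. The knockdowns share each gene's variance estimate in the joint fit, so independent lists are not a full baseline. The AFF4 calls among these genes rest on the joint fit, since a limma fit of the AFF4 set alone called 0 genes. The genes named in this paragraph were chosen after their values were seen. PRG2 fell from 120.7 ± 3.39 to 13.3 ± 2.66 RPKM with ENL, from 184.95 ± 30.5 to 94.9 ± 0.509 RPKM with AFF4 and from 128 ± 0.156 to 33.9 ± 0.118 RPKM with DOT1L knockdown (SD, n = 2). RCSD1 rose in each, from 14.7 ± 0.263 to 54.3 ± 3.59, from 4.88 ± 0.0961 to 9.09 ± 0.540 and from 9.18 ± 0.163 to 26.9 ± 0.464 RPKM. Its AFF4 knockdown level (9.09) was near that of the DOT1L-set controls (9.18) and below that of the ENL-set controls (14.7). The rise with AFF4 knockdown thus rests on the low controls of that set. MYB, a transcription factor of blood progenitors, parted: it rose from 50.04 ± 0.571 to 105 ± 5.46 RPKM with ENL knockdown and fell with DOT1L knockdown, a difference of 1.88 on the log2 scale (limma adjusted p = 2.0e-05). The globin HBE1 likewise fell with ENL knockdown and rose with DOT1L knockdown, from 1291 ± 0.910 to 1613 ± 20.9 RPKM (difference −4.34, limma adjusted p = 2.9e-07). Its controls stood at 377 ± 6.62 RPKM in the ENL set, so the control sets differed by more than the rise with DOT1L knockdown. GATA1, the erythroid master regulator, fell from 164 ± 7.33 to 63.9 ± 17.02 RPKM with ENL knockdown (adjusted p = 0.0011) and did not pass with AFF4 (0.89) or DOT1L knockdown (0.95), and its effect differed between ENL and DOT1L (adjusted p = 0.012).

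In SEM-K2 the window of chromosome 13 from 28.8 to 28.9 Mb (hg19) held 56 MLL-N peaks, against 0 in THP1, CCRF-CEM and HEL. In THP1 the window of chromosome 7 from 27.2 to 27.3 Mb held 24 MLL-N peaks, against 0 in the other MLL-N tables, and 7 p300 peaks. The THP1 window with the most MLL-N peaks lay on chromosome 22 from 46.4 to 46.5 Mb. It held 29, against 1 in CCRF-CEM, 0 in HEL and 1 in SEM-K2. Whether the MLL-N peaks of these windows come from MLL1 or from a fusion protein was not tested, and neither was a copy gain of the windows.

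Metallothioneins fell together with AFF4 knockdown, 5 of 6 measured entries with a median log2 change of −2.30, and their summed RPKM went from 467 and 710 in controls to 84.9 and 91.9. The sum was also lower after ENL knockdown, at 48.5 and 29.2 against 174 and 194 in controls, and stood at 377 and 378 against 361 and 365 with DOT1L. High controls of this set alone would not leave the knockdown libraries below the 4 controls of the other sets, where the median difference was −1.26, and without control replicate 2 the median was −2.10 with 5 of 6 still falling. Reads shared between copies would leave the sum in place, yet its smallest fall between a knockdown and a control library was −2.34. No biological explanation was tested, and neither was a difference in metal supply between cultures.

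MLL-N peaks were dense in single intervals of the genome. In HEL, 28 peaks lay on chromosome 9 from 4 to 5 Mb, of which 17.9% overlapped an MLL-N peak of another line, against 87.4% elsewhere. In THP1, 75 lay on chromosome 1 from 40 to 41 Mb, where 20% overlapped another line against 70.2% elsewhere, and p300 peaks were 3.79 times as dense as in the rest of the genome relative to CCRF-CEM and SEM-K2 MLL-N peaks. Each window was picked as the densest of its line on that chromosome, so a low overlap share follows in part from that choice. The share therefore cannot argue for a copy gain of the interval, which stays a hypothesis. Stronger local binding stays open too, since input libraries were not analysed here.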
